A study of Drosophila melanogaster with 4 samples.

How the data were processed

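Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map trimethylation of lysine 9 of histone H3 (H3K9me3), the histone mark of constitutive heterochromatin, in nuclei from heads of adult Drosophila melanogaster of the wild-type Oregon-R strain. Per the labels' protocols, flies were raised in population cages on an adult cycle of 22 days, heads were separated from whole adults with sieves, and the tissue was crosslinked with formaldehyde before sonication and immunoprecipitation. The labels give the stage as mixed adult, do not give the sex, and call the libraries a new lot without saying of what. The 4 samples are 2 ChIP libraries and 2 input libraries, and the title of each input carries the replicate number of a ChIP library. Nothing in the labels says whether the replicates came from separate cages, collections or chromatin preparations, so the spread between them may be technical.

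The files analysed were 3 lists of enriched clusters that the authors deposited: one per ChIP replicate and one for the series as a whole, called the combined set here. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Positions are on FlyBase release 5, per the file headers, which also give the lengths of 14 sequences. The cluster caller, its threshold, the use made of the inputs and the way in which the combined set was made from the replicates are not given in the sources used here. Each cluster has a start, an end and a score, and the score is the authors' deposited value per cluster. Its scale is not stated, so scores were used only to describe, rank and filter clusters. The files give no read counts, so sequencing depth is unknown and no interval was drawn from it. Wilson 95% intervals and Fisher's exact tests on shares of clusters treat clusters as independent, which neighbouring clusters are not. The Fisher p-values may therefore be too small, and they do not measure spread between animals.

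Coordinates are 1-based and inclusive, as in the deposited lists. The lists cover 13 of the 14 sequences: the arms 2L, 2R, 3L, 3R and X; chromosome 4; the 5 heterochromatic sequences 2LHet, 2RHet, 3LHet, 3RHet and XHet, together called Het here; YHet; and U, which strings together scaffolds not placed on a chromosome. Uextra has no cluster in any list and was left out. Over the lists, 10 clusters ended beyond the stated end of their sequence, by at most 860 bp, and were trimmed to it. Covered length, cluster number, width and overlap were computed with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and the figures were drawn with matplotlib 3.10.9.

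Values of the replicates are given as mean ± SD over the 2 ChIP libraries, and the combined set is given as the authors' single list with no SD. A cluster counted as found in another list when at least 1 bp overlapped. The Jaccard index is the sequence covered in both lists over that covered in either. Overlap was tested by moving the clusters of one replicate by a random distance around each sequence, with its ends joined, 10000 times; the p-value is one-sided and cannot go below 1e-04. The share of each arm's cluster sequence within 2 Mb of its centromere end was tested in the same way, with one shift for both replicates, and adjusted over the 5 arms by the Benjamini-Hochberg method. These p-values measure arrangement along a sequence, not spread between animals. Score agreement is a Spearman correlation across clusters, which are not independent. The clusters named by position followed a rule fixed before the data were examined: the 5 longest and the 5 highest-scoring clusters of the combined set, the longest on each sequence, and the longest on each arm outside the proximal 2 Mb.

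The extent of the pericentric run and the comparison of the X with the autosomal arms were added after seeing the data, as were the limits used to pick out windows dense outside the run. The run is the number of successive 100 kb windows, from the centromere end, that were at least 50% covered. The X was compared with the autosomal arms over 1 Mb blocks outside the proximal 2 Mb with a two-sided permutation test of 100000 resamples, whose smallest possible p is 1e-05; neighbouring blocks are not fully independent.

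The overlap code was checked on simulated lists: of 3155 simulated clusters on the 5 arms, 1889 had been planted to overlap and 1889 were found. Of 200 random lists on arm 2L, 8 gave a shift p of at most 0.05, against 10 due by chance. The random lists were scattered evenly and left out the widest clusters. The check therefore does not cover 2 lists that both carry a pericentric run, as the replicates do on that arm. Alternatives were a score threshold at the median of each file, a minimum width of 1 kb, joining clusters up to 1 kb apart, leaving out U, the combined set in place of the replicates, each replicate alone, stricter overlap rules (50% of the width, or of both widths) and proximal windows of 1 and 4 Mb. Gene-level comparisons had been planned and were not made: the gene table at hand is of release 6, and positions were not carried between releases. The input libraries were not analysed here beyond their labels.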

Results

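H3K9me3 was profiled by ChIP-seq in nuclei of adult Oregon-R heads, with 2 ChIP libraries and 2 input libraries. Replicate 1 had 5083 enriched clusters over 23.2 Mb and replicate 2 had 4595 over 22.9 Mb, which was 16.5% ± 0.15 (SD, n = 2) of the 13 sequences that carried clusters. The combined set of the series listed 7929 clusters over 33.4 Mb, or 23.9% of the same sequences. Clusters were mostly short with a long upper tail: the median width was 2237 bp in replicate 1 and 2257 bp in replicate 2, and the widest clusters reached 120305 and 122969 bp. The scores are those the authors deposited for each cluster; their medians were 0.83 in replicate 1, 0.89 in replicate 2 and 0.50 in the combined set.

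The first comparison asked which parts of the genome carried the mark. In the replicates, chromosome 4 and the heterochromatic sequences other than XHet were mostly inside clusters, and the long arms and XHet were mostly outside them. In the combined set XHet was mostly inside clusters, at 64.8%. The 5 Het sequences together were 72.1% ± 1.66 covered (SD, n = 2 ChIP replicates, as for the values that follow), chromosome 4 was 76.1% ± 3.46 covered, and the 5 arms were 8.38% ± 0.43 covered. The difference between the arms and either of the others was many times the SD between replicates. Het, at 8.93 Mb, made up 6.40% of the length of the 13 sequences but held 28.0% ± 0.91 of the cluster sequence. The unplaced scaffolds of U held a further 23.4% ± 0.71 and were 53.5% ± 1.12 covered. For clusters at or above the median score of their file, coverage of the arms was 4.35%, and that of 3R was 0.627% against 4.37% ± 0.45 for all clusters. In the combined set, a separate list, coverage of the arms was 15.0%.

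**Figure D1:**
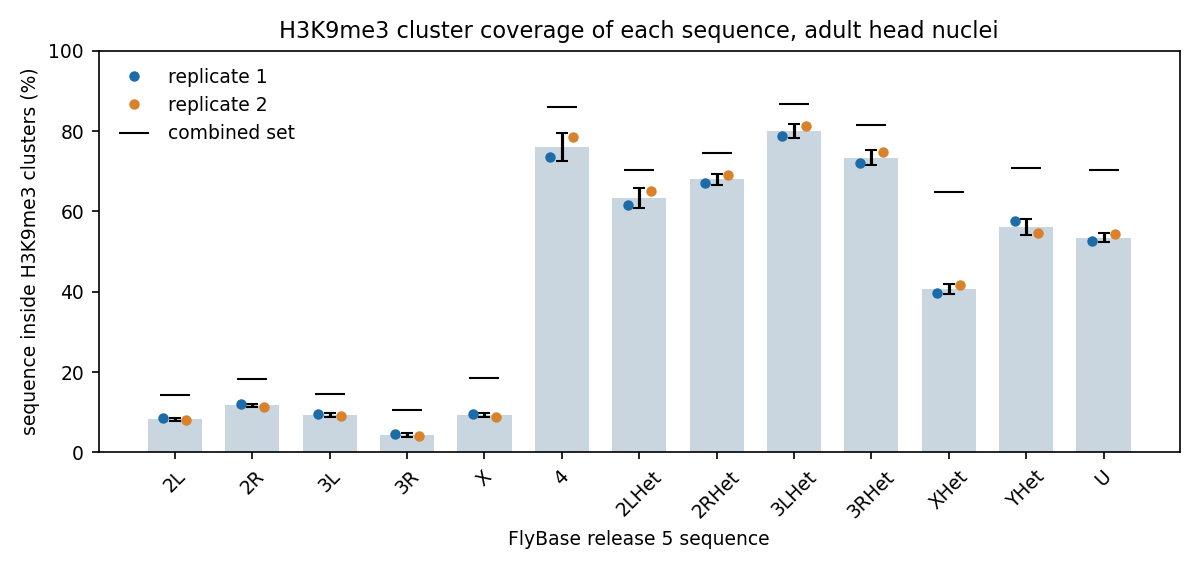
Percent of each FlyBase release 5 sequence inside H3K9me3 clusters. Bars are the mean and SD of the 2 ChIP replicates, circles the single replicates and dashes the combined set; the 5 arms lie between 4.37% and 11.7%, and XHet, the least covered of the heterochromatic sequences, is at 40.7%.

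Among the heterochromatic sequences, 3LHet was the most fully covered, at 78.7% in replicate 1 and 81.2% in replicate 2, followed by 3RHet at 73.4% ± 1.85, 2RHet at 68.0% ± 1.37 and 2LHet at 63.3% ± 2.42. XHet was 40.7% ± 1.28 covered, and YHet, from the Y chromosome carried by males only, was 56.1% ± 2.05 covered. Over the Het sequences together the median cluster width was 6100 bp ± 273 and the median score 1.60 ± 0.06, against 1995 bp ± 3.18 and 0.68 ± 0.02 on the arms. Clusters were narrower on XHet, with a median of 2373 bp ± 578 and a score of 1.24 ± 0.14, and on YHet, with 3420 bp ± 74.2 and 1.39 ± 0.12. In the combined set the median width was 2356 bp on XHet and 6865 bp on YHet, against 7548 bp on Het, so YHet differed little there. The longest cluster of the combined set, 123 kb, lay on 2RHet from 1871116 to 1994140, with a score of 1.72, and was 99.8% ± 0.16 covered by the replicates. A cluster of 122 kb on 3LHet (734802 to 856312, score 1.83) and one of 111 kb on 3RHet (1496279 to 1607286, score 1.87) came next. On 2LHet, XHet and YHet the longest clusters were 59.5 kb (150168 to 209655), 32.5 kb (154505 to 186960) and 23.0 kb (22283 to 45306), and on U the longest was 77.8 kb (1184830 to 1262582).

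The covered stretches of 2RHet were broken by long intervals that neither replicate called. Such intervals measured 114 kb (2647233 to 2761418), 109 kb (1144926 to 1254312) and 108 kb (2457396 to 2565751), and the combined set covered 0.0412%, 0.282% and 1.93% of them. The longest interval of this kind was 74.7 kb on 3RHet (447241 to 521903), 57.1 kb on 2LHet (62628 to 119699) and 47.2 kb on 3LHet (2328328 to 2375491). Assembly gaps and unmappable repeats were not examined here, and these intervals cannot be read as unmarked chromatin.

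Chromosome 4, the small dot chromosome that carries cubitus interruptus and eyeless, stood between the arms and the Het sequences in score. Its clusters had a median score of 0.98 ± 0.10 and a median width of 6091 bp ± 638 in the replicates, and of 0.53 and 3196 bp in the combined set. Its coverage was 73.6% in replicate 1, 78.5% in replicate 2 and 86.1% in the combined set. The longest chromosome 4 cluster of the combined set was 53.5 kb, from 1166916 to 1220433, with a score of 1.27, and the replicates covered 98.7% ± 0.39 of it. The longest intervals called in neither replicate were 29.3 kb (412425 to 441735), 18.9 kb (1288845 to 1307761) and 17.9 kb (502681 to 520530); the combined set covered 22.8%, 38.4% and 24.5% of them.

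The second comparison asked where along the long arms the clusters lay. On 2L, 2R and 3L the mark formed a nearly continuous block at the centromere end, and on 3R and the X the assembled arm had no such block at its end. Successive 100 kb windows at least 50% covered ran for 900 kb on 2L (22111545 to 23011544), 1600 kb on 2R (1 to 1600000) and 1500 kb on 3L (23043558 to 24543557), with the same extents in both replicates. Inside these blocks coverage was 80.1% ± 2.28 on 2L, 83.0% ± 2.72 on 2R and 84.7% ± 1.69 on 3L. In the next window outward it dropped to 25.8% ± 2.80, 11.1% ± 2.77 and 21.2% ± 8.00. The window at the centromere end was 24.7% ± 0.33 covered on 3R and 15.7% ± 0.40 on the X. These extents are counted from the end of each arm sequence, and the Het sequences are held apart from the arms. Of these, 3RHet was 73.4% covered and XHet 40.7%. How far each arm sequence reaches toward the centromere was not examined, so differences in extent cannot be read as differences between chromosomes. With 50 kb windows the run was first interrupted at 450 kb on 2L and 550 kb on 2R, so the block is not without breaks at that scale.

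**Figure D2:**
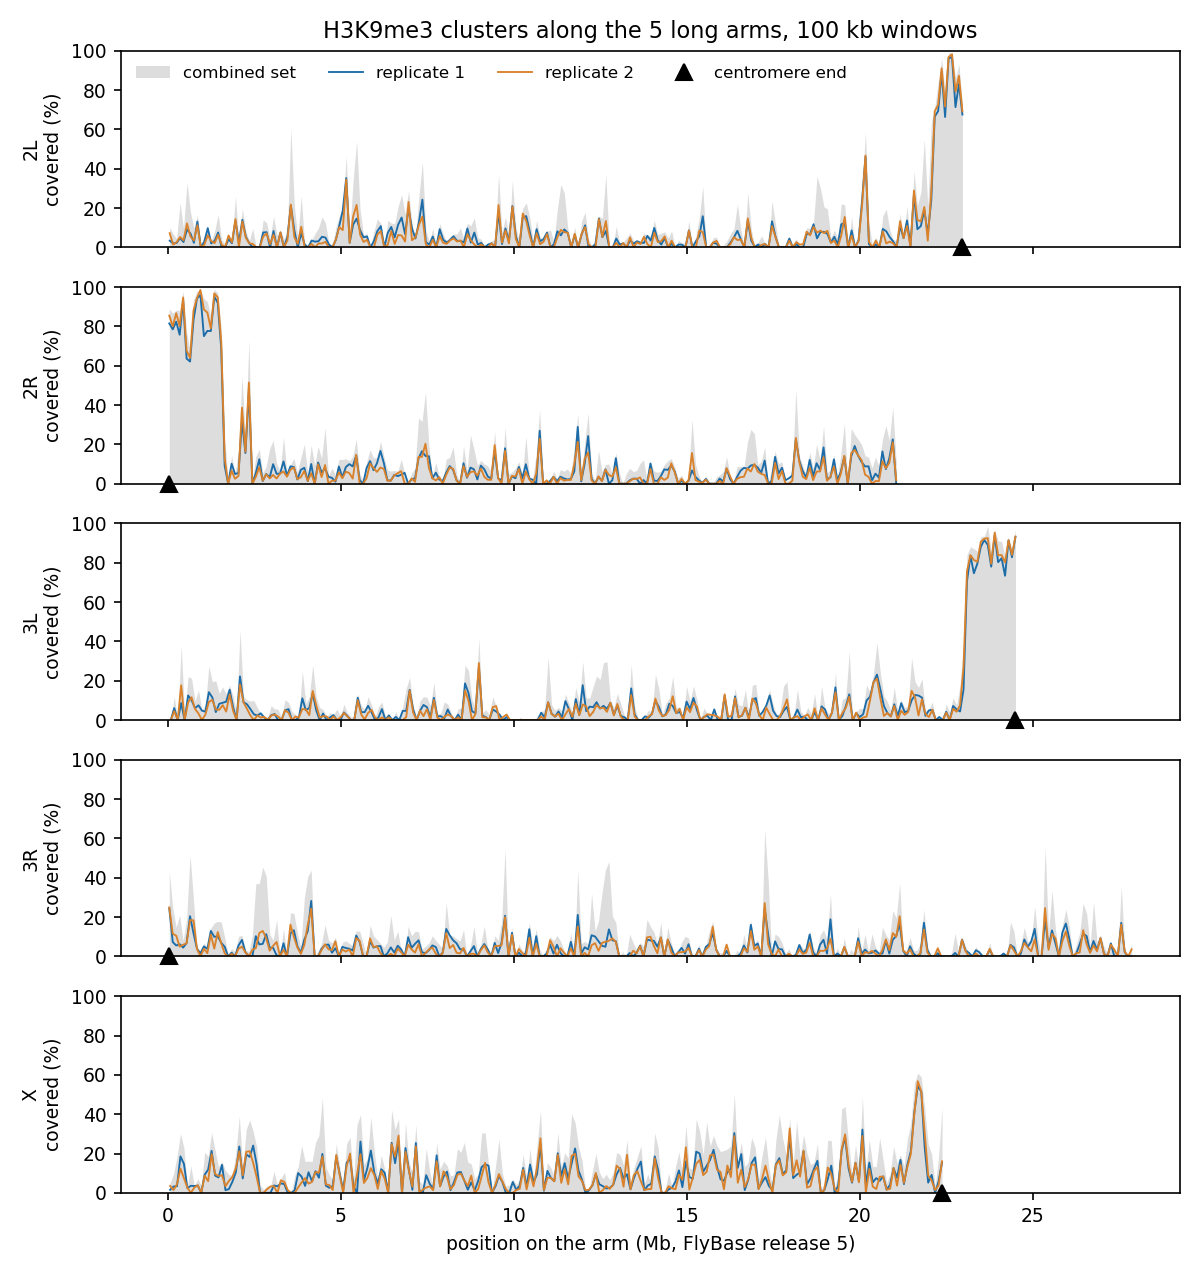
Percent of each 100 kb window inside H3K9me3 clusters (vertical axis) along the 5 long arms (horizontal axis, Mb, FlyBase release 5). Lines are the 2 ChIP replicates, the grey area is the combined set and the triangle marks the centromere end. The blocks at the ends of 2L, 2R and 3L extend over 900, 1600 and 1500 kb, and 3R and the X have none at theirs.

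The proximal 2 Mb held 42.8% of the cluster sequence of 2L in replicate 1 and 47.2% in replicate 2, 54.6% ± 3.91 of that of 2R and 57.1% ± 4.07 of that of 3L. Circular shifts of the clusters gave means of 8.60%, 9.35% and 8.07%, and the adjusted permutation p-values were 0.0217, 0.0267 and 0.0217. On 3R the proximal share was 12.3% ± 1.24 (7.17% under shifts, adjusted permutation p = 0.0302) and on the X it was 14.8% ± 0.68 (8.89%, adjusted permutation p = 0.0303). The call on 3R was lost in the combined set, where the share was 10.6% with an adjusted permutation p of 0.116. With a window of 4 Mb the shares were larger (52.5% on 2L, 62.3% on 2R, 61.7% on 3L, 21.2% on 3R and 24.5% on the X) and no arm passed the threshold. A wider window holds the whole block of 2L, 2R or 3L under more of the shifts, which raises p there. The loss of the call on these 3 arms therefore cannot be read as a weaker concentration. With clusters at or above the median score alone, the share was 73.0% on 2L, 81.0% on 2R, 89.0% on 3L and 22.3% on the X, and in the combined set it was 31.9% on 2L, 38.4% on 2R and 39.9% on 3L, all past the threshold.

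The longest clusters of the arms lay in these blocks: 109 kb on 2R (374537 to 483284, score 2.08), the one from 23831825 to 23936535 on 3L (score 1.64) and 93.5 kb on 2L (22576422 to 22669919, score 1.68). The replicates covered 99.4% ± 0.73 of the cluster on 2R and 98.9% ± 0.33 of that on 2L, and that on 3L was 96.5% and 98.4% covered. The X held its longest cluster, 39.9 kb with a score of 1.62, from 21647534 to 21687397, inside a proximal domain set back from the arm's end. The windows 21622828 to 21722827 and 21722828 to 21822827 were 55.6% ± 1.74 and 51.6% ± 0.03 covered there, and the window next to them, 21522828 to 21622827, was 40.7% ± 0.42 covered.

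Outside the blocks the arms carried scattered short clusters and a few denser domains. Of 1149 windows of 100 kb, 14 were at least 25% covered in both replicates: 8 on the X, 3 on 2L, 2 on 2R, 1 on 3L and 0 on 3R. On 2L the densest was 20111545 to 20211544, at 46.3% ± 0.50, which holds a cluster of 30.3 kb (20168768 to 20199106, score 1.58), the longest on that arm outside the proximal 2 Mb. On 2R, 2300001 to 2400000 was 49.5% ± 2.87 covered and 2100001 to 2200000 was 35.2% ± 4.87 covered. The longest clusters outside the proximal 2 Mb on the other arms were 18.0 kb on the X (2318384 to 2336399, score 1.16), 16.4 kb on 2R (9445720 to 9462087, score 0.70), 14.2 kb on 3R (14201487 to 14215677, score 0.60) and 13.5 kb on 3L (19292241 to 19305777, score 0.62). The cluster on 3R was the longest of that arm and was 68.2% ± 0.57 covered by the replicates. These autosomal clusters were weak: with clusters at or above the median score alone, the replicates covered 0% of that on 2R, 8.55% of that on 3L and 29.2% of that on 3R. At the other extreme, 913 kb of 3L (9837936 to 10751162) held no cluster in either replicate.

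The X carried more scattered clusters than the autosomal arms. Outside the proximal 2 Mb there were 35.8 ± 1.73 clusters per Mb on the X and 20.3 ± 2.43 per Mb on 2L, 2R, 3L and 3R together. Coverage there was 8.71% ± 0.55 on the X against 4.77% ± 0.57 on the autosomal arms, whose single values ran from 4.13% ± 0.49 on 3R to 5.88% ± 0.74 on 2R. The median score was 0.78 ± 0.01 on the X and 0.62 ± 0.01 on the autosomal arms, and the median widths were 1958 bp ± 36.1 and 1932 bp ± 12.4. Over 1 Mb blocks the X exceeded the autosomal arms by 3.96 percentage points (20 against 87 blocks, permutation p = 1e-05, the smallest the test allows), and by 2.84 to 4.60 points against each arm taken alone (adjusted permutation p of 0.0042 or less over the 4 arms). The difference held in each replicate; it was 7.04 points in the combined set and 1.64 points for clusters of at least 3 kb. As a ratio, coverage of the X was 1.82 times that of the autosomal arms, 1.66 times in the combined set, 1.98 times for clusters of at least 3 kb and 3.97 times for clusters at or above the median score.

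The third comparison was between the 2 ChIP replicates. They shared 19.5 Mb, a Jaccard index of 0.736, against a mean of 0.255 and a highest value of 0.320 under circular shifts (permutation p = 1e-04, the smallest the test allows). The index was 0.918 on Het, 0.885 on chromosome 4, 0.774 on U, 0.730 on YHet and 0.607 on the arms. It cannot be ranked without the coverage of each class: circular shifts alone gave means of 0.572 on Het, 0.614 on chromosome 4, 0.365 on U, 0.391 on YHet and 0.0478 on the arms. Among the arms it ran from 0.440 on 3R and 0.502 on the X to 0.699 on 2R. Shifts were not summarised for single arms, and 3R and the X lack the dense block at the centromere end. This order therefore does not rank the arms by repeatability. Each class passed the test (adjusted permutation p of 0.001 or less over 6 tests), although on YHet the highest shift reached 0.731.

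Of the replicate 1 clusters, 3825 (75.3%) were found in replicate 2, and of the replicate 2 clusters, 3632 (79.0%) were found in replicate 1. On the arms these shares were 65.1% and 72.7%, against means of 14.4% and 16.0% under circular shifts, and on Het they were 96.2% and 92.5%, against 87.0% and 87.3%. On chromosome 4 they were 95.1% and 83.5%, against means of 92.0% and 89.0% under circular shifts there, and neither passed the test (permutation p = 0.186 and 0.929). On YHet the replicate 1 share, 88.0% against 80.9% under shifts, did not pass either (permutation p = 0.124). The YHet share of replicate 2, 95.2% against 84.4%, did (permutation p = 0.0145). Wide clusters meet others more easily by chance and lie more often in the densely covered sequences, so sharing by width was set against shifts on the arms alone, a comparison added after seeing the data. There 33.7% of the replicate 1 clusters under 1.5 kb were found in replicate 2 (11.3% under shifts), and 93.2% of those of 3 to 5 kb (16.1% under shifts). For replicate 2 the values were 48.1% (12.3%) and 94.3% (17.7%), and each of these 4 shares passed the test (permutation p = 1e-04, the smallest the test allows). The arms still include the dense blocks of 2L, 2R and 3L. Shifts move clusters out of those blocks, so this comparison does not remove the effect of local density. Over all sequences, in replicate 1, 40.6% of clusters under 1.5 kb were found in replicate 2 (Wilson 95% interval 37.0% to 44.3%), 82.9% of those of 2 to 3 kb, and 450 of 450 of those of at least 10 kb. The values for replicate 2 were 49.0% (45.1% to 52.9%), 86.9% and 446 of 446.

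**Figure D3:**
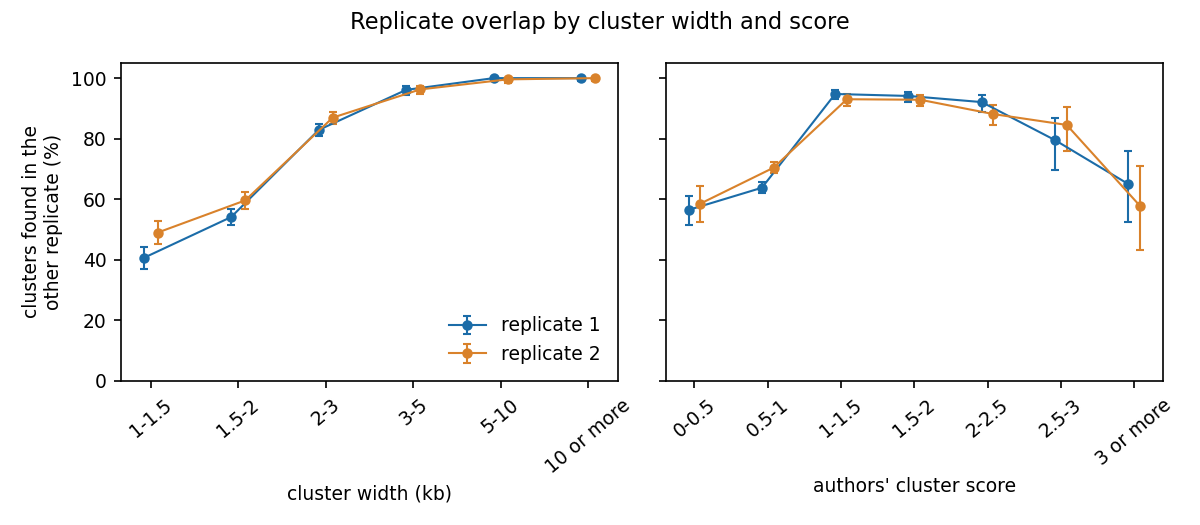
Percent of the clusters of each ChIP replicate found in the other replicate (vertical axis), by cluster width in kb and by the authors' score (horizontal axes); bars are Wilson 95% intervals. The share rises from 40.6% and 49.0% in the narrowest class to 100% at 10 kb or more, and by score it falls again to 65.0% and 57.8% in the highest class.

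Scores of overlapping clusters were correlated between the replicates, with a Spearman rho of 0.909 across 3825 pairs of clusters. Part of that range lay between kinds of sequence: within the arms rho was 0.801, within Het 0.790, within chromosome 4 0.741, within U 0.698 and within YHet 0.509. The replicate 2 score was the higher one in 86.6% of the pairs on chromosome 4, 73.2% of those on Het, 65.9% of those on YHet, 60.7% of those on the arms and 58.5% of those on U.

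The last comparison set the combined set against the replicates. It held nearly all of their clusters: 99.2% of replicate 1 and 99.3% of replicate 2. Of its own 7929 clusters, 2994 (37.8%) were found in both replicates, 1093 in replicate 1 alone, 776 in replicate 2 alone, and 3066 (38.7%) in neither. The last were short, with a median width of 1337 bp against 4238 bp for clusters found in both, and scored lower, with a median of 0.44 against 0.82. They made up 13.3% of the covered sequence of the combined set, and 89.6% of them were on the arms. The arms held 6260 of all 7929 combined clusters, with 88.55% of those found in 1 replicate and 62.0% of those found in both. Width and score were not compared within a kind of sequence, so their differences may in part reflect this mix. Coverage in the combined set was 2.41 times the replicate mean on 3R, 1.98 times on the X, 1.74 times on 2L, 1.59 times on XHet, 1.56 times on 3L, 1.55 times on 2R, 1.32 times on U, 1.26 times on YHet and 1.13 times on chromosome 4. On the other Het sequences it was between 1.08 and 1.11 times. These ratios are limited where coverage is already high, so they do not rank the sequences by added coverage. XHet went from 40.7% in the replicates to 64.8% in the combined set and U from 53.5% to 70.4%, against 4.37% to 10.5% on 3R.

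Of the 5 highest-scoring clusters in the combined set, 4 were found in neither replicate. These were on 2R (3758432 to 3760501, score 4.61) and on U (1985774 to 1987710, score 3.93; 6770971 to 6772051, score 3.93; 9788156 to 9790271, score 3.82). The other, on U (6543781 to 6546988, score 4.04), was 78.8% ± 2.25 covered by the replicates. Their widths lay between 1.08 and 3.21 kb.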

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

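Settings applied to the extent of the run and to the comparison of the X with the autosomal arms were chosen after seeing the data. The 26 values that answer a comparison were each recomputed under several settings, so the same value counts several times below. Of the recomputed values, 111 kept their call or stayed within their spread. Another 45 moved further and 6 were no longer past the threshold. Some of the 111 could not have moved, because the setting removed nothing from them. No tested difference given alternatives reversed its direction, but some untested orderings did. Chromosome 4 was covered more than Het in the replicates (76.1% against 72.1%) but less at or above the median score (67.5% against 70.7%). XHet was 40.7% covered in the replicates and 64.8% in the combined set. Combined clusters in neither replicate outnumbered those in both (38.7% against 37.8%), but not with gaps joined (35.7% against 41.2%). The spread was 1 SD between replicates (0 for the run), a Wilson 95% interval for a share of clusters or a 95% interval for rho, and a count was held to a factor of 1.5. The cause of these shifts was not tested. The minimum width of 1 kb removed no cluster. Leaving out either replicate ended no call; that values stayed within 1 SD follows from having 2 replicates. The excess of the X ranged from 1.64 to 7.04 percentage points over its alternatives, or from 1.66 to 3.97 times the coverage of the autosomal arms, and stayed past the threshold in each. No paired analysis was possible because the input libraries, which share replicate numbers with the ChIP libraries, have no cluster list here. With only clusters at or above the median score of their file, 2420 clusters per replicate were left, coverage was 4.35% on the arms, 67.5% on chromosome 4 and 12.8% over all 13 sequences, and the combined clusters found in replicate 1, replicate 2 and neither were 46.6%, 43.8% and 48.3%. With gaps of up to 1 kb joined, coverage was 55.0% on U and 16.8% over all sequences, and the combined clusters found in replicate 1, replicate 2, both and neither were 55.4%, 50.1%, 41.2% and 35.7%. Without U, coverage was 13.6%, the Spearman rho of the scores was 0.876, and the same 4 shares were 48.0%, 43.3%, 33.2% and 41.9%. The combined set in place of the replicates gave 7929 clusters and coverage of 15.0% on the arms, 86.1% on chromosome 4, 79.6% on Het, 70.9% on YHet, 70.4% on U and 23.9% over all sequences; its proximal share on 3R was 10.6%, past the threshold no longer, and its run on 2L was 1000 kb. Requiring 50% of a cluster's width gave 71.2% of replicate 1 clusters and 74.5% of replicate 2 clusters shared, and combined clusters at 47.2%, 43.2%, 31.8% and 41.4%. Requiring 50% of both widths gave 59.8% and 66.1%, then 43.2%, 39.3%, 27.2% and 44.7%, and a rho of 0.937. A proximal window of 4 Mb held 52.5% of the cluster sequence of 2L, 62.3% of 2R, 61.7% of 3L, 21.2% of 3R and 24.5% of X, all past the threshold no longer (adjusted permutation p of 0.0624 to 0.0797). With 50 kb windows the run was 450 kb on 2L, 550 kb on 2R and 1525 kb on 3L, and with windows at least 25% covered it was 950 kb on 2L and 1550 kb on 3L. The planned gene-level alternatives were not run for want of an annotation of the same release. Read depth is not in the files, so what depth alone would limit cannot be stated.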

Other observations

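The tests of score, width and unplaced scaffolds, of depth, of the whole-number ratios and of the X were chosen only after the results they concern were seen; those of small denominators and of contrast between replicates were written before. The limits used to pick out windows dense in the combined set alone were also chosen after the data were seen.

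The combined set held wide stretches of weak signal on the arms that the replicates covered far less. Of 1149 windows of 100 kb outside the pericentric runs, 13 were at least 35% covered in the combined set and under 15% covered in the mean of the replicates, and 8 of these were on 3R. On 3R, 4 successive windows from 2500001 to 2900000 were 40.1% covered by 85 combined clusters, against 9.07% ± 0.74 (SD, n = 2) in the replicates, and 2 more from 12600001 to 12800000 were 46.2% covered by 49 clusters, against 8.55% ± 1.14. The clusters there were short and weak, with median widths of 1650 and 1573 bp and median scores of 0.44 in both stretches. The highest score in them was 0.57 in the first stretch and 0.63 in the second. Which genes lie in these stretches was not examined here.

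High scores did not mark the most repeatable clusters. Clusters scored 2.5 or more were found in the other replicate less often than those scored 1.5 to 2 (73.4% against 94.1% in replicate 1, Fisher's exact p = 5.51e-12; 76.1% against 92.9% in replicate 2, Fisher's exact p = 2.25e-08). The unplaced scaffolds are not the whole cause, since outside U the difference was still -20.6 percentage points in replicate 1 and -26.0 in replicate 2 (Fisher's exact p = 0.000334 and 5.49e-07). Narrow width stays open: within 1.5 to 3 kb the difference was -14.8 points in replicate 1 (Fisher's exact p = 0.00728) and -4.59 in replicate 2 (p = 0.419). A candidate explanation is that high scores rest on few reads. Among clusters scored 2.5 or more, those whose score reduces to a ratio with a denominator of at most 3 were shared less often than the rest. In replicate 1 the difference was -40.5 points (50.8% of 63 clusters against 91.2% of 80, Fisher's exact p = 8.30e-08). In replicate 2 it was -27.8 points (36 of 60 clusters against 72 of 82, Fisher's exact p = 0.000256). A ratio of large counts can also reduce to a small denominator, so a small denominator does not show few reads. The comparison was also not held within a width class. Such ratios made up 44.1% and 42.3% of clusters scored 2.5 or more but 4.23% and 5.33% of those scored 1.5 to 2. More ratios with such denominators are available at higher scores, so this contrast may follow in part from arithmetic. It is no separate evidence of few reads. No biological explanation was tested.

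The candidate explanation of few reads rests on a property of the scores themselves. In replicate 1, 1617 of 5083 clusters carried exactly the score of another cluster, and the most common score, 0.71, occurred 45 times. Relative to that score, 100% of the tied clusters of replicate 1 and 86.2% of all its clusters were the log2 of a ratio of whole numbers with a denominator of at most 400 (relative tolerance 1e-09), against 0% of the tied clusters for each of 20 random constants. The shares of tied clusters were 100% in replicate 2 and 98.5% in the combined set. The scores may therefore be log2 ratios of read counts times one constant per file, a hypothesis that the files' headers neither state nor exclude.

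The excess of scattered clusters on the X does not come down to calls that one replicate made alone. Calls that arise at random in 1 replicate should be shared rarely. Yet outside the proximal 2 Mb, sequence covered in both replicates was 1.87 times as abundant on the X as on the autosomal arms. Over 1 Mb blocks it was 5.75% against 3.07% (permutation p = 1e-05, the smallest the test allows). The labels do not give the sex, and a lower X dose in male heads would be present in both replicates. Its effects could recur at the same places, so sharing cannot decide on dose. The share of clusters found in the other replicate was 64.4% on the X against 60.6% on the autosomal arms in replicate 1 (Fisher's exact p = 0.071) and 70.0% against 72.0% in replicate 2 (p = 0.344). An effect of X dose, repeats that map differently on the X and a real difference in the mark stay open, all untested.

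Replicate 2 covered more of 7 sequences (chromosome 4, U and the 5 Het sequences) and less of 6 (the 5 arms and YHet) than replicate 1, by 4.90 points on chromosome 4 and by -0.61 points on the arms as a whole. A difference in depth or threshold stays open: coverage moving both ways is the pattern itself, and the number of clusters was lower in replicate 2 on 12 sequences and equal on 1. A greater contrast between ChIP and input in replicate 2 stays open too. Replicate 2 had the higher score in 75.2% of 657 overlapping pairs on Het and chromosome 4, but also in 60.7% of those on the arms and 65.9% of those on YHet, which it covered less, and in 58.5% of those on U, which it covered more. The scale of the scores is not stated, and a different constant in each file would shift every pair, so these scores of single libraries do not decide it; no biological explanation was tested.

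Clusters found in neither replicate were partly below the width that the replicate lists contain at all. The narrowest cluster was 1301 bp in both replicates and 1001 bp in the combined set, and 1418 of the 3066 combined clusters found in neither replicate (46.2%) were narrower than 1301 bp.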
